A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

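Total RNA of budding yeast, extracted with hot phenol and converted to cDNA, was measured on 12 Phalanx OneArray oligonucleotide arrays with 1 colour, Cy5. The arrays form 4 groups of 3. WT and sgs1Δ cells, the latter lacking the RecQ helicase Sgs1, were each grown for 4 h at 30 °C with or without 30 µM tangeretin. Tangeretin is a methoxylated flavone of citrus peel. Its solvent DMSO was at 0.2% in all 4 groups. Both strains carry a TRP1 plasmid with the HO endonuclease gene behind the GAL1 promoter and were grown without tryptophan. Transcripts of HO or TRP1 from the plasmid and from a chromosome were not told apart. The labels do not say whether the 3 arrays of a group came from separate cultures. The file headers give the 3 arrays of a group the same sample number, as 1 RNA sample measured on 3 arrays would have. The p-values may therefore measure technical spread only.

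The raw table gives for each spot an intensity, which per the file headers is the raw intensity of 1 array and which had its background already subtracted, since the 2158 spots printed empty had a median of 0 to 1 on each array. Each spot also carries a deposited scanner flag (a column of another kind, unit other), whose value 0 was read here as detected, since the other values go with intensities near 0 or with empty spots. The value table holds log2 values normalized between arrays by the authors. Its method is not given in the sources used here. Every array in it had a median of 10, and its values correlated with the log2 raw intensity of the same array at 0.9993 to 0.9999. The scanner software is not given in the sources used here.

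Values were computed from the raw intensities. The spots of a probe were averaged, intensities under 0 were set to 0, an offset of 50 was added, control spots were left out, the arrays were quantile normalized with limma 3.58.1 in R 4.3.3, and log2 was taken. Of the 9800 spots, 6958 probes were neither controls nor empty, and 278 of these were left out because they were detected on fewer than 3 arrays. The probe with the highest mean stood for the 115 genes with several probes, which left 6185 genes. Of the probes, 6666 had a locus. The RefSeq R64 annotation of the yeast genome gave names and neighbours for 6073 of them, and 593 had no match. Chromosomes were read from systematic gene names. A probe that the file assigns to several genes (322 probes) kept a combined name such as PHO11/PHO12. Array precision is limited by the number of arrays, 3 per group.

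The 4 groups were fitted together with lmFit and eBayes of limma (8 residual degrees of freedom, 14.16 in total after moderation), without covariates. There were 5 comparisons: tangeretin against control in WT, the same in sgs1Δ, sgs1Δ against WT in control medium, sgs1Δ against WT under tangeretin, and the interaction, which is the tangeretin response of sgs1Δ minus that of WT. All p-values were two-sided and adjusted by Benjamini-Hochberg over the genes of a comparison. A gene was called at an adjusted p under 0.05. Errors of log2 changes are standard errors (SE) from this fit with n = 3 arrays per group, and other errors are standard deviations (SD). For a gene undetected in a whole group, "at least" marks a fold computed with the undetected arrays raised to the lowest detected value of the array, and for a gene at the scanner's ceiling in a whole group it marks the fold of the ceiling values.

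The choice of genes to name, 35 gene lists and the alternatives were fixed before the data were examined, apart from the exceptions given here. For the first 3 comparisons the named genes were the 8 largest rises and 8 largest falls among called genes whose arrays did not overlap between groups, and up to 4 called members of each called list. For the other two comparisons they were the 5 largest each way. SGS1, TOP3, RMI1, RNR3, HUG1, PDR5, SNQ2, TRP1, HO and GAL1 were always followed. Other list members that are named, the genes called in both strains, and the neighbours of named genes were chosen after their values were seen. The lists came from textbook knowledge and covered DNA repair, the cell cycle, stress, nutrients, metabolism and cell type. Each was tested with camera of limma at its preset correlation between genes of 0.01, with p-values adjusted over the 35 lists of a comparison, and again with a correlation estimated from the data. Called members were also counted after adjusting over the list alone.

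The alternatives were no background floor or offset, an offset of 16, 75th percentile scaling, cyclic loess normalization, leaving out the dimmest 25% of genes, no detection filter, the authors' log2 values, the mean of a gene's probes, only the groups of a comparison in the fit, replicate number as a block, eBayes with trend and robust variance, array weights, an absolute log2 change of at least 1, leaving out each array, and the estimated correlation for the lists. Brightness of the array (log2 of its median raw intensity) as a covariate, removal of a running median along the order of probes in the table, and leaving out chromosome II were chosen after seeing the data.

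The fit was tested on simulated data with 6185 genes and the design of the arrays. For tangeretin in WT it found 43 of 67 genes changed by 0.5 on the log2 scale, 66 of 67 changed by 1 and 66 of 66 changed by 2, and 5 of its 180 calls were false. For the interaction it found 35.8% of genes changed by 0.5, 80.6% of those changed by 1 and 97% of those changed by 2, and 7 of its 149 calls were false. Of 199 unchanged lists of 20 genes, 4 had an unadjusted p under 0.05 in the camera test. The noise was drawn independently for each gene and array, without the correlation between genes or the differences of array brightness in the real data. These shares of found genes and false calls are therefore not estimates for the real arrays.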

Results

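Gene expression was measured in 4 groups of 3 arrays each: WT control, WT with tangeretin, sgs1Δ control and sgs1Δ with tangeretin. The strains are MATα and auxotrophic for histidine, leucine, methionine and uracil, and sgs1Δ carries a kanMX4 marker in place of SGS1. The mean raw intensity of LEU2 was 32 to 47 in the groups, and it was detected on every array, against a median of 0 to 1 for empty spots. MET17 read 14.7 to 31.7 and was detected on the 3 sgs1Δ tangeretin arrays and on at most 1 array of each other group. URA3 read 2.67 to 10.3 and was detected on at most 1 array of a group. TRP1, which the plasmid carries, read 2880 to 7620. HIS3, which carries an internal deletion in these strains, read 19800 to 37800. SGS1 read 114 ± 6.03 (SD, n = 3) in WT control, 163 ± 10.1 in WT with tangeretin, and 5.33 ± 0.577 and 5.33 ± 1.53 in the matching sgs1Δ groups, where it was not detected on any array. The median raw intensity was 530, 548 and 814.5 on the WT control arrays, 780, 956 and 830 on the WT tangeretin arrays, 964.5, 1344 and 928 on the sgs1Δ control arrays, and 1367.5, 1530 and 1467 on the sgs1Δ tangeretin arrays. Brightness thus differed between the strains, and tangeretin arrays were on the whole brighter than control arrays of the same strain. Between 6146 and 6652 probes were detected per array (88.3% to 95.6%). After normalization, arrays of a group correlated at 0.9916 to 0.9969 across genes. WT control 3 correlated with the WT tangeretin arrays at 0.9951 to 0.9966 and with the other WT control arrays at 0.992 and 0.9916. The first principal component held 67.6% of the variance and separated the strains.

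In WT, tangeretin raised PRO3, VOA1, AQR1 and PDR5 most among the genes named by the rule, and lowered MGA1 and HSP30 most. This comparison asks which genes respond to tangeretin where Sgs1 is present. PRO3, the last enzyme of proline synthesis, rose most, by 1.56 on the log2 scale (SE 0.30, 2.96-fold, adjusted p = 0.0161, n = 3 per group). The drug efflux pump PDR5 rose by 1.16 (SE 0.15, 2.24-fold, adjusted p = 0.00234) and the multidrug transporter AQR1 by 1.20 (SE 0.28). VOA1, an assembly factor of the vacuolar proton pump, and VMA1, a subunit of that pump, rose by 1.25 (SE 0.29) and 1.11 (SE 0.27). The endoplasmic reticulum protein YET1, the SNARE YKT6 and the membrane protein TMN3 rose by 1.15, 1.08 and 1.08. MGA1, which resembles the heat shock factor, fell by 1.26 (SE 0.14, adjusted p = 0.00107), and HSP30, a stress protein of the plasma membrane, fell by 1.17 (SE 0.14). BSC1 fell by 0.97 (SE 0.10), ITT1 fell by 0.99, TDA6 fell by 0.98, JIP4 fell by 0.92, the cyclin-dependent kinase inhibitor CIP1 fell by 0.89 and MMO1 fell by 0.83.

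Of 22 measured multidrug resistance genes 6 rose in WT and none fell, and adjusted over the list alone 8 rose and 1 fell. Beside PDR5 and AQR1 these were RSB1 (0.80), GRE2 (0.53), TPO1 (0.47) and YOR1 (0.47), and the list did not pass as a group (median 0.09, adjusted p = 0.054). The lists that passed were histones (median 0.24, adjusted p = 0.027) and purine and one-carbon synthesis (median 0.24, adjusted p = 0.027), and both were lost at an adjusted p = 0.426 with an estimated correlation. Of 10 histone genes 1 rose, HTB2, which encodes histone H2B (0.38, SE 0.10, adjusted p = 0.0468), or 4 adjusted over the list alone; HHT1, for histone H3, had a change of 0.70 (adjusted p = 0.057). None of the 16 purine and one-carbon genes passed, adjusted over all genes or adjusted over the list alone; GCV2 had a change of 0.68 (adjusted p = 0.095) and ADE4 of 0.61 (adjusted p = 0.129). Among 21 DNA damage induced genes, PHR1, the photolyase, fell by 0.55 and the repair gene RAD16 fell by 0.51, or 1 rose and 4 fell adjusted over the list alone (list adjusted p = 0.88, median 0.02, but a test direction of lower). The damage reporters RNR3 (-0.50, adjusted p = 0.0597) and HUG1 (-0.33, adjusted p = 0.105) were not called. TOP3, a partner of Sgs1, read 3 to 38 in raw intensity and was not detected on any WT control array, so no comparison is given for it. SGS1 (-0.11), its other partner RMI1 (-0.11), SNQ2 (0.21), TRP1 (0.10), HO (0.46) and GAL1 (-0.24) were not called either.

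In all, 228 of 6185 genes were called in WT, 135 higher and 93 lower, of which 12 changed at least 2-fold (10 higher, 2 lower). The arrays of both groups did not overlap for 1505 genes (24.3%, against 10% by chance). The 10% holds for interchangeable arrays. Differences of array brightness could raise the share without an effect of tangeretin or strain, here and in the comparisons below. The balance of rises and falls depended on the processing: 76.3% of the calls were higher with 75th percentile scaling, 42.9% with array weights and 28.6% with array brightness in the fit. Without single arrays it was 41.4% (WT control 1), 34.6% (WT control 2), 46.6% (WT control 3), 38.7% (WT tangeretin 2) and 31% (WT tangeretin 3). The count rested on single arrays, being 26 without WT control 2, 29 without WT control 1 or WT tangeretin 3, 31 without WT tangeretin 2, 144 without sgs1Δ control 3 and 1672 without WT control 3. Only 7 calls were kept with array brightness in the fit, an alternative chosen after seeing the data. PRO3, VOA1, AQR1, VMA1, TMN3, MMO1 and HTB2 lost their calls without any 1 of WT control 1, WT control 2, WT tangeretin 2 and WT tangeretin 3. The calls of PDR5, YET1, MGA1, HSP30, ITT1, TDA6, BSC1, JIP4 and CIP1 held without any single array. With brightness in the fit all 8 named rises lost their calls, at 0.75 for PRO3, 0.69 for VOA1, 0.76 for AQR1, 0.58 for VMA1, 0.59 for TMN3, 0.67 for YKT6, 0.83 for YET1 and 0.92 for PDR5. JIP4 (-0.74), CIP1 (-0.64), MMO1 (-0.56) and HTB2 (0.38, SE 0.12, as large as without brightness) lost theirs too, while MGA1, HSP30 (-1.30), ITT1 (-1.08), TDA6 (-0.79) and BSC1 (-0.84) kept theirs, as did the rises of RSB1 (0.80) and YGR035C (1.00), the latter named after its values were seen. The histone list lost its call with 75th percentile scaling, with brightness, without chromosome II, and without WT control 1 or WT tangeretin 3, and the purine list with 75th percentile scaling, with brightness, and without WT control 1 or WT tangeretin 2.

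In sgs1Δ, sulfur and methionine genes and amino acid synthesis genes were higher as groups with tangeretin. The α cell genes MF(ALPHA)2 and SAG1 and the pump gene PDR5 rose too, but PDR5 lost its call with array brightness in the fit. This comparison asks which genes respond to tangeretin where Sgs1 is missing. ARG3 and ARG8 of arginine synthesis rose by 1.04 (SE 0.24, adjusted p = 0.0434) and 0.88 (SE 0.19). MET10, a sulfite reductase subunit, and STR3, a cystathionine beta-lyase, rose by 0.86 (SE 0.13) and 0.77 (SE 0.12). MF(ALPHA)2, an α-factor gene, rose by 0.87 (SE 0.09, adjusted p = 0.00072) and SAG1, the α-agglutinin, by 0.83 (SE 0.09). The largest rise was that of YGL072C, a dubious open reading frame beside HSF1, by 1.88 (SE 0.11, 3.69-fold, adjusted p = 5.17e-07), and ATP8, a mitochondrially encoded subunit of ATP synthase, rose by 0.90 (SE 0.13). PDR5 rose by 0.73 (SE 0.15, adjusted p = 0.0355). MIH1, the phosphatase that activates the cyclin-dependent kinase at mitosis, fell by 0.72 (SE 0.09, adjusted p = 0.00263). HO, which the plasmid carries too, fell by 0.67 (SE 0.13). The copper transporter gene CTR1 fell by 0.65, the nucleolar gene SRP40 by 0.66, the methyltransferase gene EFM2 by 0.65 and the septin gene CDC12 by 0.62. YNL162W-A fell by 0.71 and YPL068C fell by 0.64. RMI1 (-0.39, adjusted p = 0.0965), RNR3 (0.01), HUG1 (0.05), SNQ2 (0.29), TRP1 (0.06) and GAL1 (0.11) were not called.

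Of the 35 lists, 10 passed in sgs1Δ, and sulfur and amino acid synthesis kept their calls with an estimated correlation. Of 21 sulfur and methionine genes 10 rose and none fell, and adjusted over the list alone 10 rose (median 0.34, adjusted p = 1.55e-11, and adjusted p = 0.00214 with an estimated correlation); MET5 and MET3 rose by 0.74 and 0.70. Of 28 amino acid synthesis genes under Gcn4, the activator of general amino acid control, 3 rose, which were ARG3, ARG8 and HOM3 (0.61), or 15 adjusted over the list alone (median 0.27, adjusted p = 2.12e-09, and adjusted p = 0.0105 with an estimated correlation). Of 5 α cell genes 2 rose, or 4 adjusted over the list alone (median 0.44, adjusted p = 6.06e-06), with an adjusted p = 0.138 with an estimated correlation. Of 18 iron uptake genes 3 rose, or 4 adjusted over the list alone: ENB1 (0.65), FIT2 (0.49) and FET3 (0.39). The iron list had a median of 0.15 (adjusted p = 0.00381), with an adjusted p = 0.138 with an estimated correlation. PDR5 and the acid efflux pump PDR12 (0.43) were the 2 of 22 multidrug resistance genes that rose, the same number as adjusted over the list alone (median 0.12, adjusted p = 0.00402), with an adjusted p = 0.144 with an estimated correlation. GCV3 (0.68) and IMD2 (0.52) were the 2 of 16 purine and one-carbon genes that rose, or 6 adjusted over the list alone (median 0.24, adjusted p = 0.00519), with an adjusted p = 0.189 with an estimated correlation. One of 22 general stress genes rose, the small heat shock protein gene HSP26 (0.60), or 3 higher and 1 lower adjusted over the list alone, and GRE1 had a change of 0.38 (adjusted p = 0.0815). The stress list had a median of 0.17 (adjusted p = 0.00216), with an adjusted p = 0.137 with an estimated correlation.

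Lists of the G1/S transition and of ribosome biogenesis moved down in sgs1Δ with tangeretin. CDC21, the thymidylate synthase (-0.48), and the G1 cyclin PCL1 (-0.46) were the 2 of 19 G1/S genes that fell, or 5 adjusted over the list alone (median -0.21, adjusted p = 0.0022), with an adjusted p = 0.0568 with an estimated correlation. None of 32 ribosome biogenesis genes was called, or 6 lower adjusted over the list alone (median -0.15, adjusted p = 0.0193), with an adjusted p = 0.144 with an estimated correlation; EBP2 had a change of 0.48 and RRP9 of -0.41, both short of the threshold. None of 7 a cell genes was called, or 2 higher adjusted over the list alone (median 0.27, adjusted p = 0.0103), with an adjusted p = 0.265 with an estimated correlation; AGA2 had a change of 0.52 and STE2 of 0.33. In all, 97 genes were called, 50 higher and 47 lower, of which 2 rose at least 2-fold. The arrays did not overlap for 1560 genes (25.2%, against 10% by chance). Of the calls 71.6% were higher with 75th percentile scaling, 65% with cyclic loess, 88.9% with array brightness in the fit and 45.1% with the dimmest genes left out. The count was between 20 and 63 without any 1 of WT control 1 and 2, WT tangeretin 2, sgs1Δ control 1 and 3 and the 3 sgs1Δ tangeretin arrays, 244 without WT control 3 and 785 without sgs1Δ control 2. Every sgs1Δ tangeretin array was brighter than every sgs1Δ control array. Only 16 calls were kept with array brightness in the fit, an alternative chosen after seeing the data. All 97 kept their sign with brightness, and their median size went from 0.54 to 0.47 and their median SE from 0.10 to 0.12. PDR5 lost its call without sgs1Δ control 1 or 3 or sgs1Δ tangeretin 1 or 3, and ARG3, ARG8, CDC12, CDC21, PCL1, PDR12, HSP26, FET3, GCV3 and IMD2 without any 1 of sgs1Δ control 1 and 3 and the 3 sgs1Δ tangeretin arrays. The calls of YGL072C, ATP8, MF(ALPHA)2, SAG1, MET10, STR3, MET5, MET3, ENB1 and MIH1 held without any single array. With brightness in the fit YGL072C, ATP8, MF(ALPHA)2, SAG1, MET5, FIT2, FET3, MIH1 and CTR1 kept their calls and the other genes named in sgs1Δ lost theirs. Of these ARG3 was at 0.49, GCV3 at 0.42 and PDR5 at 0.49, while HO (-0.74), ENB1 (0.66), EFM2 (-0.64), PDR12 (0.47), STR3 (0.71) and MET3 (0.62) stayed about as large. Without sgs1Δ control 2 the iron, multidrug, purine, a cell and ribosome biogenesis lists lost their calls, and without sgs1Δ tangeretin 1 the a cell and ribosome biogenesis lists.

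**Figure D1:**
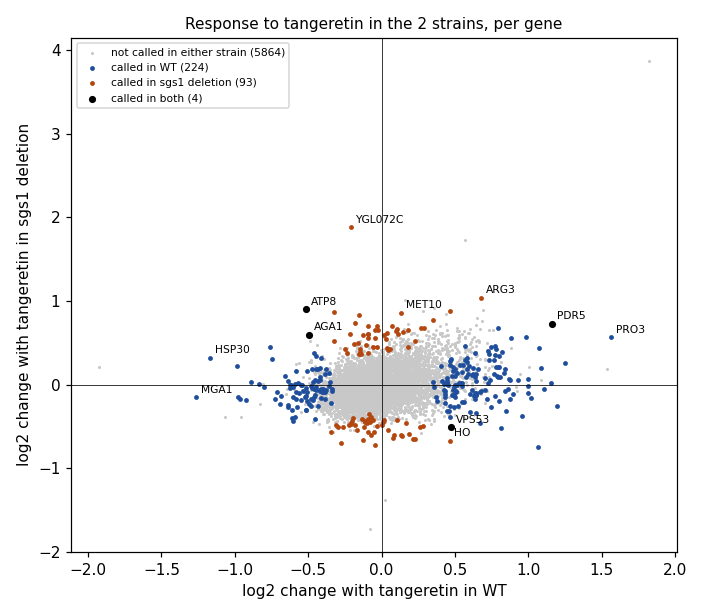
Log2 change with tangeretin in sgs1Δ against that in WT, each point a gene, with the genes called in WT, in sgs1Δ and in both marked. Across 6185 genes r was 0.316. PDR5 was the 1 gene called higher in both strains, and it lost both calls with array brightness in the fit.

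The responses of the strains were then compared, to ask whether the loss of Sgs1 changes the response to tangeretin. PDR5 was the 1 gene called in the same direction in both strains. ATP8 (-0.52 in WT, 0.90 in sgs1Δ), AGA1 of a-agglutinin (-0.50 and 0.59) and VPS53 of vesicle tethering (0.47 and -0.51) were called in opposite directions. With array brightness in the fit PDR5 lost its call in both strains, at 0.92 in WT and 0.49 in sgs1Δ, and ATP8, AGA1 and VPS53 lost theirs in WT. Independent calls would give 1.09 genes higher in both strains and 0.707 lower in both. Of the 228 WT calls 136 (59.6%) had the same sign in sgs1Δ, and of the 97 sgs1Δ calls 51 (52.6%) had the same sign in WT. The log2 changes of both strains correlated across 6185 genes at r = 0.316 (Spearman's rho 0.308), where genes are not independent replicates, and at -0.10 with array brightness in the fit.

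The interaction was largest for YGL072C at 2.09 (SE 0.16, adjusted p = 1.29e-05, n = 3 per group), followed by HSP30 at 1.48 (SE 0.20), ATP8 at 1.42 (SE 0.18), ITT1 at 1.21 (SE 0.18) and YOR053W at 1.20 (SE 0.21), all higher in the sgs1Δ response than in the WT response. It was lowest for PBI2, an inhibitor of vacuolar proteinase B, at -1.81 (SE 0.32, adjusted p = 0.0146), PBR1 at -1.33 (SE 0.21), the ribosomal protein gene RPL24B at -1.33 (SE 0.26), RGP1 at -1.16 (SE 0.25) and HO at -1.14 (SE 0.18). PDR5 had an interaction of -0.44 (adjusted p = 0.341), so a difference between the strains was not detected for it. RMI1 (-0.28), RNR3 (0.51), HUG1 (0.38), SNQ2 (0.08) and TRP1 (-0.04) were not called. In all, 81 genes were called, 38 higher and 43 lower, of which 19 differed at least 2-fold (9 higher, 10 lower). The balance turned with 75th percentile scaling (55.6% higher), cyclic loess (54.9%) and the authors' values (65.1%), and ranged from 33.8% without sgs1Δ tangeretin 3 to 73.3% without WT tangeretin 2.

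Among lists, 11 passed in the interaction, and the sulfur list alone kept its call with an estimated correlation. Of 21 sulfur and methionine genes 4 were higher, MET5 (0.92), MET3 (0.74), MET2 (0.72) and the sulfate permease gene SUL2 (0.61), or 12 higher and 1 lower adjusted over the list alone (median 0.42, adjusted p = 2.39e-08, and adjusted p = 0.00658 with an estimated correlation). Of 5 α cell genes 2 were higher, or 4 adjusted over the list alone (median 0.68, adjusted p = 2.24e-06), with an adjusted p = 0.0993 with an estimated correlation. Of 22 general stress genes 1 was higher, or 7 adjusted over the list alone (median 0.19, adjusted p = 0.0002), with an adjusted p = 0.0622 with an estimated correlation. Of 32 ribosome biogenesis genes 1 was lower, or 2 adjusted over the list alone (median -0.19, adjusted p = 0.000914), with an adjusted p = 0.0622 with an estimated correlation. The other lists were G1/S genes (median -0.18, adjusted p = 0.00305, and adjusted p = 0.0622 with an estimated correlation), amino acid synthesis (0.18, 0.00308, and adjusted p = 0.0993 with an estimated correlation) and proteasome (-0.12, 0.00308, and adjusted p = 0.124 with an estimated correlation). Further lists were a cell genes (0.32, 0.00308, and adjusted p = 0.288 with an estimated correlation), nitrogen catabolite repressed genes (0.21, 0.00892, and adjusted p = 0.364 with an estimated correlation). The last were ergosterol synthesis (-0.11, 0.021, and adjusted p = 0.0993 with an estimated correlation) and histones (-0.16, 0.0324, and adjusted p = 0.43 with an estimated correlation). The number of genes called was between 14 and 47 without any 1 of WT control 1 and 2, WT tangeretin 2 and 3, sgs1Δ control 1 and 3 and sgs1Δ tangeretin 1 and 2, 200 without sgs1Δ control 2 and 367 without WT control 3, and was 209, with all 81 kept, with array brightness in the fit. Tangeretin arrays were brighter than control arrays by a similar amount in both strains, so this covariate could hardly move the interaction. The median size of its calls was 0.77 before and after, and keeping them does not exclude brightness. Across genes the interaction correlated at -0.43 with the brightness component of the WT arrays, the main pattern of deviation within their groups. With that of the sgs1Δ arrays it correlated at 0.24. Without WT control 3 the amino acid list lost its call, without sgs1Δ control 2 the ergosterol, proteasome and histone lists. Without any 1 of WT control 1 and 2, WT tangeretin 3, sgs1Δ control 3 and sgs1Δ tangeretin 1 the histone list lost its call again. PBI2, RPL24B and RGP1 lost theirs without any 1 of WT control 1 and 2, WT tangeretin 2 and 3 and sgs1Δ control 3.

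The strains differed far more from each other than either did from its tangeretin arrays. This comparison asks which genes depend on Sgs1, or differ between these strains otherwise, in control medium. SGS1 itself fell by 2.17 (SE 0.12, at least 4.5-fold, adjusted p = 5.82e-09, n = 3 per group). Phosphate starvation genes were higher in sgs1Δ: PHO89, a phosphate transporter gene, by 4.45 (SE 0.16, 21.9-fold), SPL2, a regulator of phosphate uptake, by 3.92 (SE 0.09, 15.1-fold) and the acid phosphatase genes PHO11/PHO12 by 3.35 (SE 0.09, 10.2-fold). The α-factor gene MF(ALPHA)1 was higher by 3.59 (SE 0.11, 12-fold), the cell wall mannoprotein genes DAN1 and TIR1 by 3.32 and 2.73, PBI1 by 3.86 and YMR317W by 3.69. Zinc starvation genes were lower: ZPS1 fell by 5.58 (SE 0.09, 47.9-fold), the zinc transporter gene ZRT1, which was at the ceiling on all WT arrays, fell by 4.81 (SE 0.08, at least 28-fold) and ADH4 fell by 2.78 (SE 0.10). ARO9 of aromatic amino acid breakdown fell by 2.64 (SE 0.12), ARO10 of the same pathway fell by 2.85 (SE 0.10), YGL072C fell by 3.03 (SE 0.11), and YAR066W/YHR214W fell by 2.23 (SE 0.08).

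Phosphate, ergosterol and zinc genes kept their list calls with an estimated correlation. All 12 measured phosphate starvation genes were higher, as they were adjusted over the list alone (median 0.96, adjusted p = 9.61e-10, and adjusted p = 0.00359 with an estimated correlation), VTC3 by 1.65. Of 9 zinc starvation genes 7 were lower, as adjusted over the list alone (median -0.98, adjusted p = 7.22e-06, and adjusted p = 0.00976 with an estimated correlation), IZH1 at -1.47. Of 24 ergosterol synthesis genes 17 were higher, ERG28 (1.72), ERG3 (1.56), ERG8 (1.36) and their activator UPC2 (1.30) among them, and HMG2 was lower (-0.40), the same counts as adjusted over the list alone (median 0.70, adjusted p = 1.31e-07, and adjusted p = 0.00359 with an estimated correlation). Of 5 α cell genes 4 were higher, MF(ALPHA)1, MF(ALPHA)2 (2.47), the a-factor receptor gene STE3 (1.70) and SAG1 (1.01), and 4 adjusted over the list alone (median 1.70, adjusted p = 7.83e-05, and adjusted p = 0.144 with an estimated correlation). Of 7 a cell genes 4 were higher, MFA1 (1.23), AGA2 (0.91), STE6 (0.37) and MFA2 (0.32), and 4 adjusted over the list alone (median 0.32, adjusted p = 0.0362, and adjusted p = 0.347 with an estimated correlation).

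Stress, protein turnover and DNA damage genes were higher on balance in sgs1Δ. The proteasome, chaperone and DNA damage lists lost their calls with array brightness in the fit. The general stress genes DDR2 (2.73), HSP26 (2.10), HSP12 (1.86) and GRE1 (1.57) were among 10 of 22 that were higher while 4 were lower, or 12 and 4 adjusted over the list alone (median 0.29, adjusted p = 0.00681, and adjusted p = 0.13 with an estimated correlation). Chaperone genes were higher for 10 of 21 and lower for 1, as adjusted over the list alone (median 0.26, adjusted p = 0.0107, and adjusted p = 0.238 with an estimated correlation), with HSP78 at 1.23, SSA3 at 1.06 and YDJ1 at 1.00. Of 31 proteasome genes 11 were higher and none lower, as adjusted over the list alone (median 0.25, adjusted p = 0.00241, and adjusted p = 0.13 with an estimated correlation), with RPT1 at 0.93, PRE9 at 0.92, PRE7 at 0.86 and RPN5 at 0.99. With array brightness in the fit HSP78 was at 0.11, YDJ1 at 0.13, RPT1 at 0.58, PRE9 at 0.67 and RPN5 at -0.19, and these lost their calls. Of 21 DNA damage induced genes 7 were higher and 3 lower, as adjusted over the list alone (median 0.19, adjusted p = 0.0436, and adjusted p = 0.13 with an estimated correlation). The polyubiquitin gene UBI4 (1.55), HUG1 (1.29, SE 0.12, adjusted p = 1.63e-06), an inhibitor of ribonucleotide reductase, and DDR48/YMR173W-A (1.14) were higher, and PHR1 (-0.69) and the ribonucleotide reductase gene RNR3 (-0.54, adjusted p = 0.00608) were lower, though PHR1 (-0.18) and RNR3 (-0.40) lost their calls with brightness in the fit. RMI1 (0.21) was not called.

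Sulfur genes were higher for 14 of 21 and lower for 3, as adjusted over the list alone (median 0.52, adjusted p = 0.00241, and adjusted p = 0.0541 with an estimated correlation), with STR3 at 1.51, MET14 at 1.04, MET28 at 0.85 and the S-methylmethionine permease gene MMP1 at -1.22. The sulfur list had a median of 0.34 without chromosome II. Iron uptake genes were higher for 11 of 18 and lower for 2, or 12 and 2 adjusted over the list alone (median 0.41, adjusted p = 0.00241, and adjusted p = 0.13 with an estimated correlation); the siderophore transporter gene SIT1 (2.29), FTH1 (1.32), the heme oxygenase gene HMX1 (1.30) and CCC2 (0.77) were higher, and FIT1 (-0.57) and FIT3 (-0.50) were lower. PDR5 (0.49), TRP1 (0.42), HO (0.42) and GAL1 (0.60) were higher and the efflux pump gene SNQ2 (-0.61) was lower. With brightness in the fit PDR5 was at 0.08, SNQ2 at -0.16, TRP1 at 0.30 and HO at 0.30, and these lost their calls. In all, 2998 genes (48.5%) were called, 1337 higher and 1661 lower, of which 288 differed at least 2-fold (202 higher, 86 lower). The balance turned with brightness in the fit (60.3% higher) and cyclic loess (51.5%), and with the order of probes removed (50.7%). The arrays did not overlap for 3197 genes (51.7%, against 10% by chance). All sgs1Δ control arrays were brighter than all WT control arrays, and 715 calls were kept with array brightness in the fit, an alternative chosen after seeing the data, with which the proteasome, chaperone and DNA damage lists lost theirs. Of the 2998 calls 2810 kept their sign, and their median size went from 0.50 to 0.33 and their median SE from 0.11 to 0.17. Without sgs1Δ control 1 the DNA damage list, the a cell list and HO lost their calls, and so did the a cell list without WT control 3, HO without WT control 1 and PDR5 without WT control 2 or sgs1Δ control 2 or 3.

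**Figure D2:**
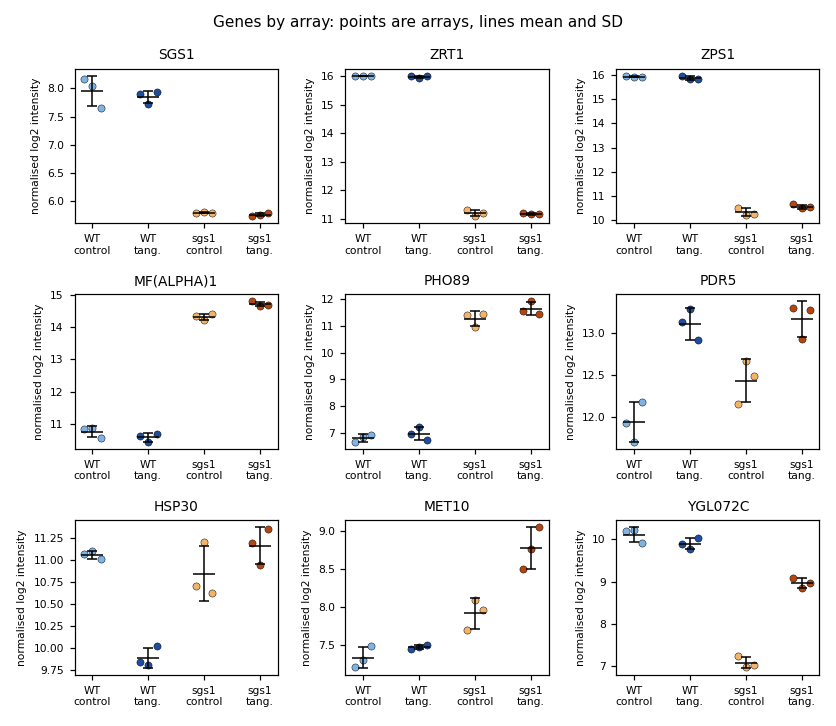
Normalized log2 intensity of selected genes on each array, in the 4 groups of 3 arrays, each point 1 array, with mean and SD as lines and axes that do not start at 0. SGS1, PHO89, ZRT1 and MF(ALPHA)1 separate the strains in both media, and PDR5 is higher with tangeretin in both strains.

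Genes of chromosome II stood out in the comparison of the strains. Over its 400 genes the median difference in control medium was 0.73 (SD 0.49, 1.66-fold), with 333 higher, 8 lower and 59 not called in sgs1Δ, while the medians of the other chromosomes lay between -0.12 and 0.04. Under tangeretin the median was 0.68 (SD 0.53, 1.6-fold), with 324 higher and 5 lower. Elsewhere 974 of 5499 genes (17.7%) were higher in control medium, against 83.2% on chromosome II. The 6 sgs1Δ arrays had chromosome II medians of 0.69 to 0.74 relative to WT control, and the WT arrays of -0.01 to 0.03. Without chromosome II, a choice made after seeing the data, 2609 genes were called in control medium, 979 higher and 1630 lower. The chromosome was left out only after normalization over all probes, and the median of the remaining genes was -0.056. How far normalization made the excess of lower genes was not tested. The 3 higher members of the DNA damage checkpoint list, 3 of the 4 higher histone genes and 3 of the 7 higher homologous recombination genes lie on chromosome II, as does PHO89 of the phosphate list. PHO5 of that list lies there too, but its probe, shared with PHO3, was not counted to a chromosome. HSP26, SSA3, PRE7 and FTH1, named as members of other lists, lie on chromosome II too, as does GAL1, whose difference of 0.60 was below the median of the chromosome.

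**Figure D3:**
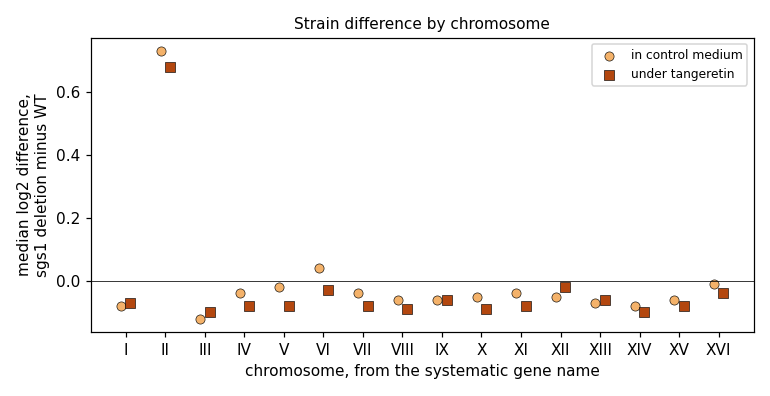
Median log2 difference of sgs1Δ minus WT for the genes of each chromosome, in control medium and under tangeretin. Chromosome II lies at 0.73 and 0.68, and the other chromosomes lie between -0.12 and 0.04.

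Under tangeretin the difference between the strains was much like that in control medium. This comparison asks how the strains differ when both are treated. SGS1 was lower by at least 4.12-fold in sgs1Δ (log2 -2.09, SE 0.12). PHO89 (4.66, SE 0.16), MF(ALPHA)1 (4.16, SE 0.11), PBI1 (4.05), SPL2 (3.84) and MF(ALPHA)2 (3.67) were higher, and ZPS1 (-5.30, SE 0.09), ZRT1 (-4.80, at least 27.8-fold), ADH4 (-2.81), ARO10 (-2.78) and the copper transporter gene CTR1 (-2.46, SE 0.10) were lower. HUG1 (1.67), TRP1 (0.37) and GAL1 (0.94) were higher and HO (-0.72) and SNQ2 (-0.53) lower, while PDR5 (0.06), RNR3 (-0.02) and RMI1 (-0.06) were not called. With array brightness in the fit SNQ2 was at -0.09 and TRP1 at 0.26, and both lost their calls. Of 2042 genes called in both media 2022 had the same direction, 887 higher and 1135 lower, where independent calls would give 278 and 418. Across genes the differences of both media correlated at 0.847.

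Under tangeretin 14 of the 35 lists differed between the strains, and 7 kept their calls with an estimated correlation. These included phosphate starvation (12 of 12 higher, median 1.12, adjusted p = 1.44e-10), zinc starvation (8 of 9 lower, median -1.31, adjusted p = 3.87e-07), sulfur and methionine (15 of 21 higher and 1 lower, median 0.90, adjusted p = 3.87e-07) and general stress (17 of 22 higher and 2 lower, median 0.46, adjusted p = 2.72e-06). The others of the 7 were iron uptake (13 of 18 higher and 2 lower, median 0.51, adjusted p = 1.64e-05), ergosterol synthesis (14 of 24 higher and 1 lower, median 0.61, adjusted p = 2e-05) and amino acid synthesis (15 of 28 higher and 1 lower, median 0.53, adjusted p = 0.000115). Adjusted over the list alone these were 12 phosphate genes higher, 8 zinc genes lower, 15 sulfur genes higher and 1 lower, 18 stress genes higher and 2 lower, 13 iron genes higher and 2 lower, 16 ergosterol genes higher and 1 lower, and 17 amino acid genes higher and 1 lower. The α cell genes (4 of 5 higher, median 2.37, adjusted p = 1.92e-06) had an adjusted p = 0.0678 with an estimated correlation. The a cell genes (6 of 7 higher, or 7 adjusted over the list alone, median 0.65, adjusted p = 0.000216) had an adjusted p = 0.117 with an estimated correlation. Nitrogen catabolite repressed genes (14 of 21 higher and 2 lower, median 0.58, adjusted p = 0.000244) had an adjusted p = 0.118 with an estimated correlation. Ribosome biogenesis genes (19 of 32 lower and 2 higher, median -0.35, adjusted p = 0.00302) and G1/S genes (11 of 19 lower and 3 higher, median -0.46, adjusted p = 0.00957) both had an adjusted p = 0.0585 with an estimated correlation. Chaperone genes (10 of 21 higher and 3 lower, median 0.23, adjusted p = 0.0121) had an adjusted p = 0.205 with an estimated correlation. Cell wall integrity genes (7 of 15 higher and 1 lower, median 0.18, adjusted p = 0.0324), with PIR3 at 1.72 and CWP1 at -2.20, had an adjusted p = 0.149 with an estimated correlation. In all, 2842 genes (45.9%) were called, 1286 higher and 1556 lower, of which 286 differed at least 2-fold. The balance turned with brightness in the fit (57.5% higher), cyclic loess (53.2%) and the order of probes removed (50.7%). The arrays did not overlap for 3561 genes (57.6%, against 10% by chance). All sgs1Δ tangeretin arrays were brighter than all WT tangeretin arrays, and 992 calls were kept with array brightness in the fit, where the chaperone list lost its call. Of the 2842 calls 2706 kept their sign, and their median size went from 0.50 to 0.38 and their median SE from 0.11 to 0.16. The cell wall list lost its call with 75th percentile scaling and without sgs1Δ tangeretin 2, and both lists lost theirs with the dimmest genes left out.

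**Figure D4:**
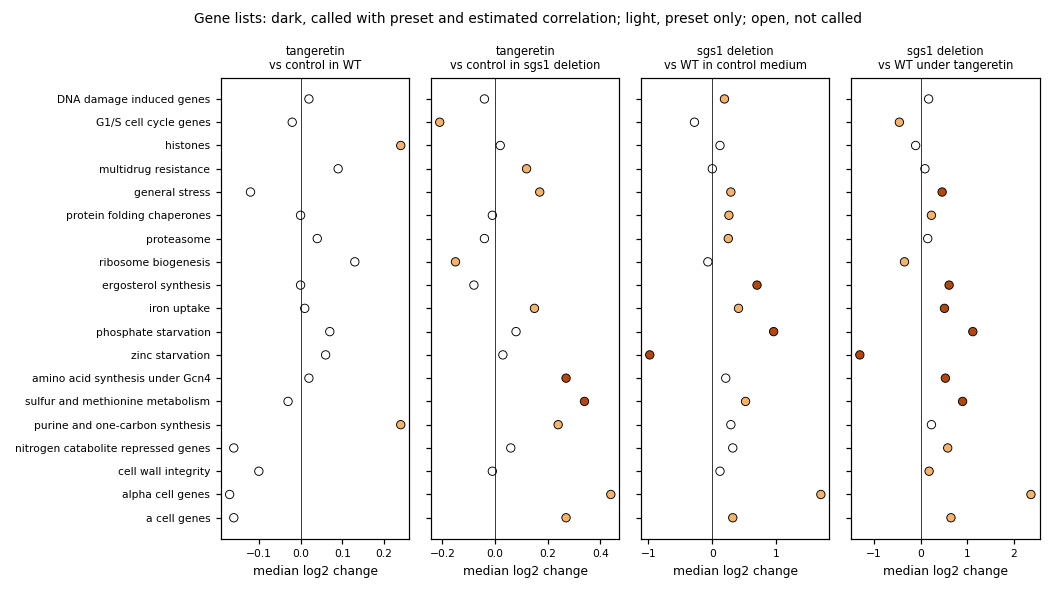
Median log2 change of the gene lists that passed the camera test in at least 1 comparison, for each comparison but the interaction, with filled points for lists that passed and dark ones for those that passed with an estimated correlation too. Phosphate and zinc lists differ between the strains in both media, and the sulfur list is higher in sgs1Δ with tangeretin, at a median of 0.34.

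**Figure D5:**
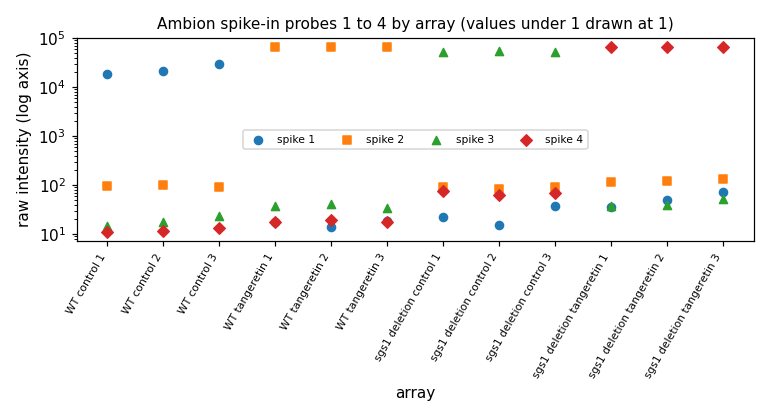
Raw intensity of the Ambion control spikes on each array, on a log axis. A different one of spikes 1 to 4 is bright in each group, between 23050 and 65469 on average, and that spike is at 124 or lower on average in the other groups.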

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

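Of the tests given here, the correlation between neighbouring probes and those on spikes, a cells and diploid cells were chosen only after the result was seen, as were array brightness as a covariate of the fit and removal of the order of probes.

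The interaction test called 81 genes, at which the change between control and tangeretin arrays differed between the strains. Without single arrays the count ranged from 14 to 367. A part of array brightness in these calls was not excluded, so they do not establish a different response to tangeretin. The largest differences, sgs1Δ minus WT, were 2.09 for YGL072C, 1.48 for HSP30, 1.42 for ATP8, 1.21 for ITT1, 1.20 for YOR053W, -1.81 for PBI2, -1.33 for PBR1, -1.33 for RPL24B, -1.16 for RGP1 and -1.14 for HO. Among gene lists, the interaction passed with a median of 0.42 for sulfur and methionine metabolism, 0.68 for α cell genes, 0.32 for a cell genes, 0.21 for nitrogen catabolite repressed genes, 0.19 for general stress and 0.18 for amino acid synthesis under Gcn4. With an estimated correlation the sulfur list kept its call (adjusted p = 0.00658) and the others lost theirs, at an adjusted p = 0.0993, 0.288, 0.364, 0.0622 and 0.0993 in that order. It passed in the other direction for ribosome biogenesis (-0.19), G1/S genes (-0.18), histones (-0.16), the proteasome (-0.12) and ergosterol synthesis (-0.11). These lists lost their calls with an estimated correlation, at an adjusted p = 0.0622, 0.0622, 0.43, 0.124 and 0.0993 in that order. Of 100 drawn of the 200 distinct ways to split the arrays, 4 called as many genes, the real one included, but with part of the splits drawn this share lies too near 0.05 to exclude chance firmly. The highest other split called 947, which points to a structure of the arrays: it set WT control 3 with WT tangeretin 2 and 3.

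Probes for Ambion control spikes lie outside the measurement of yeast genes, and a different one was bright in each group. Ambion spike 1 averaged 23050 in WT control and 17 to 52 in the other groups. Spike 2 averaged 65469 in WT tangeretin and 88 to 124 elsewhere, and spike 3 averaged 53076 in sgs1Δ control and 19 to 43 elsewhere. Spike 4 averaged 65465 in sgs1Δ tangeretin and 12 to 70 elsewhere. The bright spike of a group was the same on its 3 arrays, as it would be with 1 RNA sample per group. That does not settle whether cultures were separate. Differences in preparation between groups cannot be told apart from those of tangeretin or strain.

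The response of WT to tangeretin was measured against control arrays of unequal brightness, of which WT control 3 lay closer to the tangeretin arrays than to the other control arrays. Against position in the table as the cause of these calls speaks that the change of neighbouring probes correlated at 0.059 and that 226 of the 228 calls were kept, among 783, with the order of probes removed; the same correlation was 0.197 for tangeretin in sgs1Δ and 0.247 for the interaction, where 96 of 97 and 80 of 81 calls were kept among 433 and 302, and why the counts rose was not tested. Array brightness stays open: the WT change correlated at 0.16 with the brightness component of the sgs1Δ arrays, and 7 of the 228 calls were kept with brightness as a covariate, where the median size of the called changes went from 0.57 to 0.40 and their median SE from 0.12 to 0.14, so that calls ended through both; the sgs1Δ change correlated at 0.35 with the component of the WT arrays, above the bound set beforehand for brightness as a cause in WT, and 16 of its 97 calls were kept, but all 97 kept their sign and their median size went only from 0.54 to 0.47, with a median SE from 0.10 to 0.12. The WT change correlated at 0.77 with the brightness component of the WT arrays themselves, the arrays from which the change was computed. All 228 WT calls kept their sign with brightness as a covariate. Tangeretin itself and brightness cannot be told apart for most of these genes, since the tangeretin arrays were brighter than 2 of the 3 control arrays. The split of the 6 WT arrays by brightness, WT control 1 and 2 and WT tangeretin 1 against the rest, called 698 genes, more than the real 228 and pointing to the same structure, and 2 of the 10 splits called as many as the real one, which are too few for a share under 0.05.

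α-factor, zinc and phosphate genes differed between the strains in both media. Arrays put into a wrong group after the spikes were added are argued against, since 0 arrays shared their brightest spike with another group. An exchange of cultures or RNA before that step would not show in the spikes. An excess of a cells in WT is argued against by a cell genes, which were higher in sgs1Δ by a median of 0.32. An excess of diploid cells in WT is argued against by haploid and pheromone pathway genes, at a median of -0.20. Both values are differences between the strains, so they cannot speak to such cells in both strains or mainly in sgs1Δ. That was not tested. With array brightness in the fit 19 of the 23 called members kept call and direction, and all 23 kept their direction. Their median size went from 1.4 to 1.17, which leaves a part in brightness open. Over all genes, the difference in control medium correlated at 0.43 with the brightness component of WT arrays and at 0.2 with the sgs1Δ one. Under tangeretin these correlations were 0.19 and 0.33, so brightness stays open here too. Loss of Sgs1 may account for the block, but with 1 strain that carries the deletion it cannot be told apart from other differences between the strains.

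For the other comparisons 10 splits are too few for a share under 0.05. Tangeretin in sgs1Δ called 97 genes against at most 1 in another split, with 1 of 10 splits as high. The strains in control medium gave 2998 against at most 1, and under tangeretin 2842 against at most 0, each with 1 of 10 as high.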

How the results depend on the processing

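Array brightness, the order of probes and leaving out chromosome II were alternatives chosen after seeing the data. The number of genes called for tangeretin in WT, 228, was 105 without floor and offset, 93 with the authors' values, 53 with only the groups compared, 2614 with array weights, 12 with a log2 change of at least 1, 7 with brightness and 783 with the order of probes removed. For tangeretin in sgs1Δ, 97 became 61 without floor and offset, 64 with an offset of 16, 62, 32, 1651, 2, 18 and 433 with the same further alternatives in that order. For the interaction, 81 became 43 without floor and offset, 43 with the authors' values, 1582 with array weights, 19 with a log2 change of at least 1, 209 with brightness and 302 with the order of probes removed. For the strains in control medium, 2998 became 288 with a log2 change of at least 1 and 791 with brightness, and under tangeretin 2842 became 286 and 1108. A change of at least 1 lowers a count by its construction, and the cause was not tested for the others.

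Leaving out each array gave 26 to 1672 genes for tangeretin in WT, 20 to 785 in sgs1Δ, 2263 to 3290 for the strains in control medium, 2325 to 3061 under tangeretin and 14 to 367 for the interaction. The WT count was 29 without WT control 1, 26 without WT control 2, 1672 without WT control 3, 31 and 29 without WT tangeretin 2 and 3, and 144 without sgs1Δ control 3. The sgs1Δ count was 63, 60 and 244 without WT control 1, 2 and 3, 58 without WT tangeretin 2, 22, 785 and 22 without sgs1Δ control 1, 2 and 3, and 20, 37 and 31 without sgs1Δ tangeretin 1, 2 and 3. The interaction count was 17, 14 and 367 without WT control 1, 2 and 3, 15 and 34 without WT tangeretin 2 and 3, 47, 200 and 17 without sgs1Δ control 1, 2 and 3, and 19 and 33 without sgs1Δ tangeretin 1 and 2. The number of lists called ranged over 0 to 3 for WT, 5 (without sgs1Δ control 2) to 12 for sgs1Δ, 9 to 13 and 13 to 16 for the strains, and 8 to 12 for the interaction. For WT it was 0 without WT control 1 and 1 without WT tangeretin 2.

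The number of lists called for WT was 0 with 75th percentile scaling and 1 with brightness, which was neither histones nor purine synthesis, and with an estimated correlation they were 0, 2, 3, 7 and 1 for the 5 comparisons. The correlation of the responses, 0.32, was reversed to -0.10 with brightness and ranged from 0.22 to 0.41 without single arrays, against a jackknife SD over arrays of 0.182. TOP3 between the strains in control medium was reversed from 0.14 to -0.40 with 75th percentile scaling, but its probe was detected on 0 of 3 WT and 1 of 3 sgs1Δ arrays, so neither value measures it, and RPN5 was reversed to -0.19 with brightness. Of 130 called values of named genes, 120 stayed called in the same direction with 75th percentile scaling, 85 with brightness and 76 with a log2 change of at least 1. Leaving out single arrays ended the call of a named gene in 157 cases and other alternatives in 172. Values not called that stayed so with a changed sign were counted as unchanged. Signal over background limits dim genes, whose changes the offset of 50 shrinks towards 0.

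The replicate numbers did not pair the arrays, since deviations of the same number correlated at 0.52, -0.31 and 0.22 in WT and at 0.30, -0.42 and -0.21 in sgs1Δ. With them as a block, 480 genes were called for WT, 93 for sgs1Δ, 3027 and 2900 for the strains, and 126 for the interaction.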

Other observations

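The test of parts of chromosome II was chosen only after the result was seen, as were array brightness and the order of probes as terms of the fit, and the tests on the probe of YGL072C.

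Lists that passed in none of the 5 comparisons included those closest to the known work of Sgs1. In control medium 7 of 25 homologous recombination genes were higher in sgs1Δ and 4 lower, as adjusted over the list alone (median 0.14, adjusted p = 0.31). The higher ones included RDH54 (1.40) and SLX1 (1.00), both acting on recombining DNA and both on chromosome II, where 3 of the 7 lie, and the list median was 0.08 without that chromosome. The lower ones included SAE2 (-0.74), of end resection, and RAD55 (-0.58). Of 15 DNA damage checkpoint genes 3 were higher and 3 lower (median -0.08, mean 0.12, adjusted p = 0.80). One of 5 end joining genes was higher (adjusted p = 0.65), and 4 of 12 genes of telomere maintenance and silencing were higher and 2 lower (adjusted p = 0.229). Tangeretin in WT gave adjusted p = 0.91 for homologous recombination, 0.984 for the checkpoint, 0.719 for end joining and 0.271 for telomeres, and in sgs1Δ it gave 0.0739, 0.321, 0.235 and 0.425.

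Of the metabolic lists that passed in no comparison, the respiratory chain came closest between the strains in control medium, with 12 of 27 genes lower in sgs1Δ and 2 higher (median -0.20, adjusted p = 0.0763). Oxidative stress genes were higher for 9 of 19 and lower for 2 (adjusted p = 0.0676). Glycolysis (adjusted p = 0.641), genes of the TCA and glyoxylate cycles (0.641), galactose utilisation (0.925, median -0.04, mean 0.02, and a median of -0.31 without chromosome II), thiamine synthesis (0.641), the unfolded protein response (0.864), single copy ribosomal proteins (0.34), G2/M genes (0.769), M/G1 genes (0.589), haploid and pheromone pathway genes (0.418) and meiosis genes (0.313) did not pass.

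Genes of chromosome II were higher in sgs1Δ than in WT. Its median difference of 0.73, the largest of any chromosome in either medium, is consistent with an extra copy of the chromosome in part or all of the sgs1Δ cells, a hypothesis found and tested on the same data, for which DNA content was not used here. A gain of part of the chromosome only is argued against by its 10 equal parts, the lowest of which had a median of 0.64 in control medium. Array brightness and the order of probes are argued against as the whole cause, since the median stayed at 0.67 with brightness and 0.75 with the order of probes in the fit. Whether the gain came with the loss of Sgs1 or separately cannot be told from 1 strain.

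A release of genes near chromosome ends was tested as a hypothesis on the 10 outermost tested genes of each of 32 arms. Probes assigned to several genes, such as PHO11/PHO12, and undetected probes were left out, so the genes they read were not covered. The median difference of the 320 outermost genes minus that of the other 5579 was -0.08 in control medium, with 60 higher and 107 lower. This argues against a general release among the genes covered. Under tangeretin 80 were higher and 81 lower.

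YGL072C read 79 to 98 on the sgs1Δ control arrays and 639 to 861 on the other 9 arrays. HSF1, which lies beside it, changed by -0.20 (SE 0.09) with tangeretin in sgs1Δ, and the probes next to that of YGL072C in the table changed by between -0.26 (SAL1) and 0.32 (SDS24). MMS2, which lies beside MF(ALPHA)2, was lower in sgs1Δ by -1.91 (SE 0.10) in control medium and -2.10 (SE 0.10) under tangeretin. Beside SGS1, GCV2 was higher at 0.59 and 0.67 (SE 0.23 each), and SPG5 was at 0.24 and 0.13 (SE 0.09 each).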
